A study of Homo sapiens with 4 samples.

How the data were processed

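Poly-A RNA of MG63 and U2OS cells was sequenced as paired-end reads from TruSeq V2 libraries, per the labels' protocols. That kit does not mark the strand of a transcript, so reads of a gene and of a gene on the opposite strand cannot be told apart where they overlap. The group of each library was taken from its title and stated treatment, although the treatment text names B5 for all 4 samples. The libraries are 1 of MG63 with B5, 1 of untreated MG63, 1 of U2OS with B5 and 1 of untreated U2OS. The dose of 10 µM and the time of 48 h come from that text, and whether the untreated cells received a vehicle is not given in the sources used here. Nothing states how many cultures stand behind a library, so p-values of single genes measure only the spread between these samples.

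The submitters' processing notes name Trimmomatic 0.27, FastQC 0.10.1, TopHat2 2.0.8 and Partek 6.6, with human builds of the GRCh37 generation and a mouse build. The deposited table carries other coordinates, since 47593 of its 58825 genes have exactly the start and end of GENCODE release 29 on GRCh38 and 58552 of its identifiers are in that release. All coordinates are therefore given as the table gives them, on GRCh38, and the aligner, annotation and counter behind its values are not given in the sources used here. Per the file headers, the authors deposited FPKM values and a read count for each gene and library. The deposited counts divided by the FPKM kept nearly the same ratio between libraries for well-counted genes, so gene lengths hardly differed between libraries, while genes with few counts could depart from it. Genes with a count of 0 carry an FPKM of 0.0001. Because FPKM divides by all reads of a library, a change in a few abundant transcripts, such as the mitochondrial ones, shifts all other genes. Columns that could not be matched to a sample numbered 0.

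Total counts per library were 77802821, 80147273, 70681123 and 76331318, in the order given above. They leave counting error small for most genes above 1 FPKM, and a count of 0 allows up to 3 counts. Short loci can rest on few counts, such as PVRIG2P with 101 counts at 1.14 FPKM in untreated U2OS. Shares of counts were given 95% Wilson intervals.

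Genes with a mean of at least 1 FPKM over all 4 libraries were kept, which left 12885. Per line, the change was log2((FPKM with B5 + 1)/(FPKM untreated + 1)), which understates changes of genes with low values, and genes at least 2-fold higher or lower on that scale were counted without a test. The difference in response was the U2OS change minus the MG63 change. Overlap between lines was set beside the product of both counts divided by the number of genes.

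The design fixed before the data were examined foresaw limma on log2(FPKM + 1) with the cell line as a block, and edgeR were the table to hold counts. It did, so edgeR's quasi-likelihood test on the deposited counts (TMM scaling, cell line plus treatment, 1 residual degree of freedom) was the main test of B5 and, from the same fit, of U2OS against MG63. limma with a trended prior was an alternative. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05, and the SE of an edgeR log2 change is its size divided by the square root of its F statistic. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

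In all, 46 gene lists were fixed before the data were examined, from textbook knowledge, and 41 had at least 5 tested members. Each was tested with limma camera on the cross-line fit with a preset correlation of 0.01, adjusted over the 41 lists. Its p-value then compares the genes of a list with all other genes, so genes and not libraries act as the replicates. Per line, a list's median was given as a percentile among 10000 random lists of its size matched on mean expression in 20 bins.

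Named genes followed a rule fixed before the data were examined. It took the 10 genes furthest above and the 10 furthest below the untreated level per line and, by the smaller change, in both lines; the 8 and 8 with the largest difference between lines, the 6 and 6 with the largest difference in response, up to 4 members of each described list, line identity genes, ACTB and GAPDH. Clone names and small RNA loci were left out, as the rule set, and genes of the Y chromosome are not reported. A gene was called uncertain where at least 50 bp of its exons overlap those of another gene in GENCODE release 29, where its name joins those of a pair of genes (readthrough), or where it is a pseudogene. For an overlapped gene the change with the overlapping genes added was the log2 ratio of their summed CPM plus 0.5. Where an overlapping gene is much more abundant, this sum follows that gene. A small change of the sum then cannot tell moved reads from a real change of the scarcer gene.

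The tests were tested on simulated counts drawn for the 12885 genes, with 100 of them changed 4-fold and another 100 changed 16-fold. With dispersion constant at 0.05, edgeR and limma each recovered 99% of the former and 100% of the latter for B5, with 18 unchanged genes called by each. With a dispersion varying widely between genes they recovered 0% of either for B5, and also 0% of either for U2OS against MG63. The deposited counts gave 5126 calls for that line comparison, so this simulation is no measure of the power in these data. How many responding genes the design could find is thus not known. A count of 0 from it does not show that no gene responded.

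Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-ratio scaling, rescaling of each library to the same sum (TPM), a 3-fold threshold, limma settings, the cell line left out, and an estimated correlation in camera. Chosen after seeing the data were DESeq2, edgeR with DESeq2-type size factors or with library size only, camera on the counts, rescaling of each library to the mean FPKM sum (which, unlike TPM, keeps the weight of the pseudocount), and the 5967 protein-coding genes without an exon-overlapping gene.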

Results

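RNA sequencing was used to ask how the transcriptomes of a pair of human osteosarcoma cell lines differed after exposure to an active compound known only by its code name, B5. MG63 and U2OS are established lines grown from malignant bone tumours, and MG63 is described in the labels as osteoblast-like. Each line was sequenced once after 48 h with 10 µM B5 and once untreated, giving 4 libraries in 4 groups with 1 library per group. Total counts over genes were 77802821 in MG63 with B5, 80147273 in untreated MG63, 70681123 in U2OS with B5 and 76331318 in untreated U2OS. The mitochondrial genome took a smaller share of the counts after B5 in both lines. Its share was 12.7% (95% Wilson interval 12.659 to 12.673) in untreated MG63 and 10.0% (10.006 to 10.02) with B5, and 10.8% (10.794 to 10.808) in untreated U2OS and 6.93% (6.9195 to 6.9314) with B5. These intervals cover counting error only. On log2(FPKM + 1) the treated and the untreated library of a line correlated across genes at 0.972 in MG63 and 0.951 in U2OS, while libraries of different lines correlated at 0.695 to 0.720, genes not being independent replicates. With no replicate cultures, every per-line difference below is a difference between 2 libraries without a replicate check.

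In MG63, genes known to be induced by low oxygen stood out among those lower with B5. NDRG1, a stress-responsive gene of the hypoxia programme (chromosome 8, 133237171 to 133297958, GRCh38), had 337 FPKM untreated and 56.6 with B5, a log2 change of -2.55. ANGPTL4, a secreted inhibitor of lipoprotein lipase (chromosome 19, 8363289 to 8374370), had 40.4 and 4.44 FPKM, a log2 change of -2.93. CITED2, a transcriptional coregulator that competes with HIF1A for its coactivators, had 29.3 and 4.03 FPKM (log2 -2.59), and FJX1 had 5.30 and 0.161 FPKM (log2 -2.44). Of the 22 measured genes in the list of hypoxia and HIF targets, 20 were lower with B5 in MG63, 9 of them at least 2-fold. The list's median log2 change of -0.67 lay at percentile 0 among 10000 expression-matched random lists, as a description of these libraries. P4HA1, a prolyl hydroxylase subunit that modifies collagen, went from 65.5 to 19.7 FPKM (log2 -1.69). Glycolysis genes were also lower, 14 of 19 of them, with a median of -0.12 at percentile 0.29. With each library rescaled to the same FPKM sum it became -0.04, while the median of all genes went to 0.12. In U2OS 12 of the 19 glycolysis genes were higher, with a median of 0.14, and the list did not pass camera across both lines (adjusted p = 0.298).

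Outside pseudogenes, readthrough loci and loci that overlap others, the gene furthest above its untreated level in MG63 was GPX1, a glutathione peroxidase that reduces hydrogen peroxide (chromosome 3, 49357176 to 49358353), with 9.67 FPKM untreated and 83.9 with B5, a log2 change of 2.99. The annotation used to find overlaps gives GPX1 1430 bp of exons, more than its deposited span holds. That GPX1 overlaps no other gene therefore rests on a gene model other than the deposited one. B3GALT6, a galactosyltransferase of proteoglycan linker synthesis, went from 0.691 to 11.7 FPKM (log2 2.91). Its 2816 bp of exons fill its whole span, and counting of few-exon genes in separate pieces stays open, as described below. CHAMP1, a zinc finger protein of chromosome alignment, went from 0.791 to 9.98 FPKM (log2 2.62). Cell cycle genes moved by less and in the same direction. Of the 40 measured genes of the G1/S transition and DNA replication, 39 were higher with B5 in MG63, with a median log2 change of 0.49 at percentile 100. ORC1, a subunit of the origin recognition complex, had 7.76 and 15.8 FPKM, and CDC25A, a phosphatase that activates cyclin-dependent kinases, had 3.39 and 6.28 FPKM. Of the 40 genes of G2/M and mitosis, 39 were higher as well, with a median of 0.32 at percentile 99.99. Across both lines the G2/M list did not pass camera (adjusted p = 0.968). CCNA2, which encodes cyclin A2, had 49.9 FPKM untreated and 82.8 with B5. Of 23 cholesterol synthesis genes 21 were higher, with a median of 0.35 at percentile 99.97, including DHCR7 (log2 1.05) and IDI1 (log2 1.04). In U2OS 11 of them were higher and 12 lower, with a median of -0.01, and the list did not pass camera across both lines (adjusted p = 0.428).

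Across the 12885 genes with a mean of at least 1 FPKM, 139 were at least 2-fold higher and 163 at least 2-fold lower in MG63 with B5 than without. Which direction held more genes depended on the scaling, being 131 higher and 203 lower (39.2% higher) with median-ratio factors and 161 and 144 (52.8% higher) with each library rescaled to the same FPKM sum, against 46.0% in the main setting. Several of the largest values are uncertain because reads of one locus can be counted under another. RPL17-C18orf32 had 0 counts untreated and 2199 with B5, FMC1-LUC7L2 had 0 and 2357, and HSPE1-MOB4 had 557 and 0, and all are readthrough loci that overlap their parent genes. UPK3BL1, ZNF664, TIGD1, LRP11, CA9, BCL2L2 and ZBED1 share exonic sequence with another annotated gene. With the overlapping genes added, the log2 change in MG63 went from 3.46 to -0.03 at UPK3BL1, from -2.77 to -0.08 at LRP11, from 2.42 to 0.37 at TIGD1 and from -2.16 to -0.95 at ZBED1, while it was kept at ZNF664 (2.49 and 2.81) and BCL2L2 (-2.39 and -1.98). A small change of such a sum can also come from an abundant overlapping gene, so it does not show that the named gene was unchanged. MTND1P23, TUBBP1 and RPL32P29 are pseudogenes. The counts depended on the pseudocount, being 285 higher and 345 lower with 0.1 in place of 1 and 49 and 51 with 5, and were 50 and 69 among 5967 protein-coding genes without an exon-overlapping gene, a subset chosen after seeing the data.

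**Figure D1:**
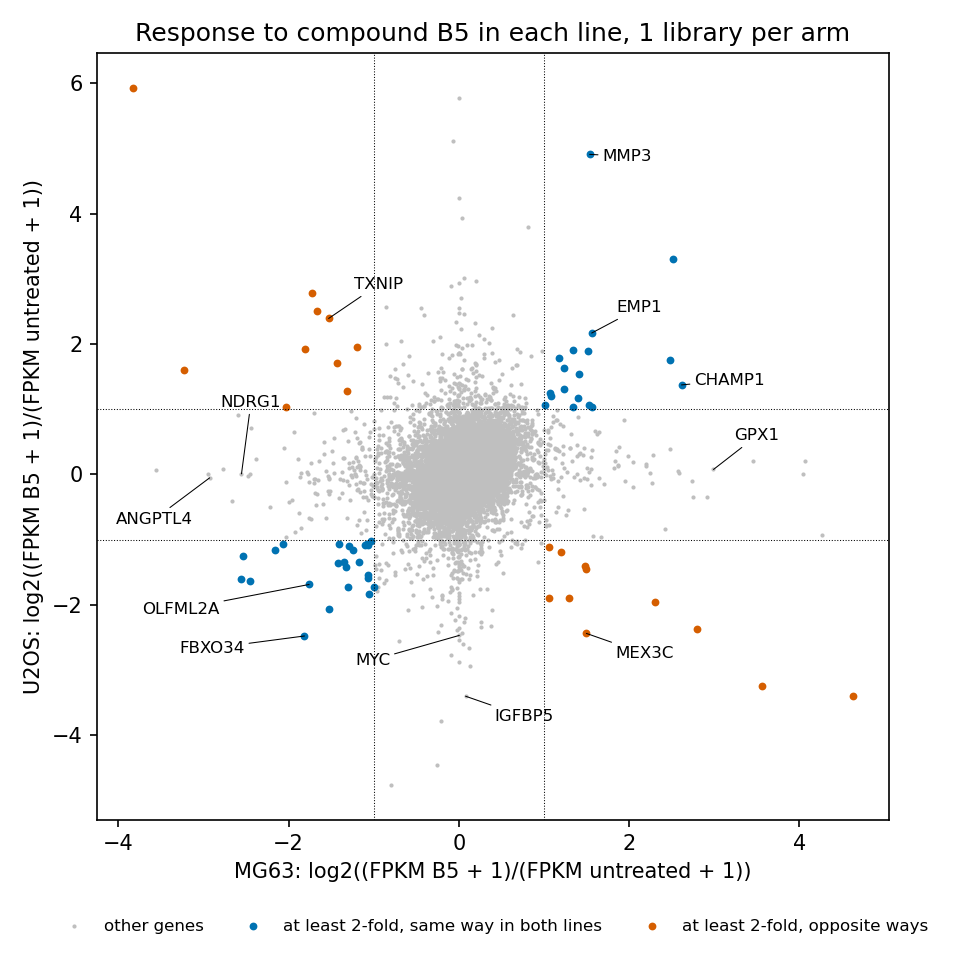
Each point is 1 of the tested genes, with its log2((FPKM + 1)/(FPKM + 1)) ratio of B5 over untreated in MG63 on the horizontal axis and in U2OS on the vertical axis, from 1 library per arm. Dotted lines mark 2-fold; 42 genes passed it the same way in both lines (18 higher and 24 lower) and 21 in opposite ways.

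In U2OS, the gene furthest above its untreated level with B5, outside loci that overlap others, was MMP3, which encodes stromelysin-1, a secreted metalloproteinase of matrix turnover (chromosome 11, 102835801 to 102843609). It had 2.75 FPKM untreated and 112 with B5, a log2 change of 4.91. ESM1, a secreted proteoglycan, went from 0.409 to 10.0 FPKM (log2 2.97). Amino acid and stress response genes formed the group with the highest list median. All 29 measured genes of the ATF4 integrated stress response were higher with B5 in U2OS, 13 of them at least 2-fold, and their median log2 change of 0.82 lay at percentile 100 among 10000 matched random lists. TRIB3, a pseudokinase of the ATF4 response, went from 6.14 to 30.4 FPKM (log2 2.14), and DDIT3, which encodes the transcription factor CHOP, from 6.07 to 28.3 FPKM (log2 2.05, and 0.69 with its 3 exon-overlapping genes added). PPP1R15A, the phosphatase subunit that reverses eIF2alpha phosphorylation, went from 16.5 to 59.1 FPKM (log2 1.78), and SLC7A11, the cystine transporter subunit, from 3.22 to 13.3 FPKM (log2 1.76).

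MYC, the proto-oncogene transcription factor (chromosome 8, 127735434 to 127742950), was among the genes furthest below their untreated level in U2OS, with 13.2 FPKM untreated and 1.56 with B5 (log2 -2.47). TNNC1, cardiac troponin C, went from 26.1 to 2.53 FPKM (log2 -2.94), DKK3, a secreted glycoprotein of the dickkopf family, from 41.2 to 6.23 FPKM (log2 -2.55), and FBXO34, an F-box protein, from 11.2 to 1.19 FPKM (log2 -2.48). IGFBP5, a secreted binding protein of insulin-like growth factors, went from 32.3 to 2.15 FPKM (log2 -3.40), and the keratin gene KRT75 from 37.5 to 5.39 FPKM (log2 -2.59), and both share exonic sequence with another gene. Cell cycle genes had lower values rather than higher ones. Of the 40 genes of G2/M and mitosis 33 were lower with B5 in U2OS, with a median of -0.19 at percentile 0, among them KIF20A (log2 -0.91), and the median became -0.05 with each library rescaled to the same FPKM sum. Of the 40 genes of G1/S and DNA replication 25 were lower, with a median of -0.05 at percentile 0.65, which became 0.10 with each library rescaled to the same FPKM sum while the median of all genes went to 0.21. Chaperones of the endoplasmic reticulum were lower too, 17 of 25 of them, with a median of -0.29 at percentile 0, for example PDIA4 (log2 -0.83) and HSP90B1 (log2 -0.69). That median became -0.145 with the same rescaling. In MG63 13 of these chaperone genes were higher and 12 lower, with a median of 0.01, and the list did not pass camera across both lines (adjusted p = 0.0631).

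In U2OS, 278 genes were at least 2-fold higher and 268 at least 2-fold lower with B5 than without, so that 50.9% of them were higher. This split depended on the scaling, being 204 higher and 298 lower (40.6% higher) with median-ratio factors and 423 and 201 (67.8% higher) with each library rescaled to the same FPKM sum. That last scaling, chosen after seeing the data, moved the median of all genes from 0.05 to 0.12 in MG63 and from 0.09 to 0.21 in U2OS, whereas median-ratio factors left it at 0.01 and 0.02. With a pseudocount of 0.1 the U2OS counts were 503 and 480, with 5 they were 72 and 76, and among protein-coding genes without an exon-overlapping gene they were 113 and 119. Changes at loci that overlap other genes are uncertain, and the change of the sum follows the more abundant gene. With the overlapping genes added, the log2 change in U2OS went from 5.77 to 0.01 at BLOC1S5-TXNDC5 (0 and 13656 counts), from 3.94 to 0.48 at RSC1A1, from 3.79 to 0.84 at SENP3-EIF4A1, from 2.56 to 0.34 at NDUFC2-KCTD14, from 2.79 to 0.99 at ABHD14B and from -2.76 to -0.11 at TUBA1A. It was kept at DCDC2C (2.93 and 3.55), ZNF114 (2.90 and 3.55) and ZNF146 (2.71 and 2.77). The pseudogenes MTCO1P12 and MTND1P23 have near-identical copies.

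Both lines changed some of the same genes at least 2-fold, in the same way and in opposite ways. At least 2-fold higher in both were 18 genes, where independent lists of these sizes would share 3.00, and at least 2-fold lower in both were 24, where 3.39 would be shared. In opposite ways 21 were changed, against 6.41 for independent lists. In this setting there was thus an excess in opposite ways too, though a smaller one than in a shared direction. The order turned at a 3-fold threshold, with 2 genes higher and 4 lower in both and 9 changed in opposite ways. It also turned with a pseudocount of 5 (3, 1 and 7), while in the other settings genes changed the same way were the more numerous. EMP1, an epithelial membrane protein (chromosome 12, 13196723 to 13219941), was at log2 1.56 in MG63 and 2.17 in U2OS. MMP3 went from 7.48 to 23.6 FPKM in MG63 beside its 2.75 to 112 in U2OS, and CDKN2D, an inhibitor of CDK4 and CDK6, from 1.39 to 5.39 and from 0.314 to 2.81. LURAP1L (log2 1.24 and 1.63) and SAR1A, a GTPase of vesicle export from the endoplasmic reticulum (1.40 and 1.18), were also higher in both. Lower in both were FBXO34 (log2 -1.81 and -2.48), the extracellular matrix protein gene OLFML2A (-1.76 and -1.69), the m6A reader gene YTHDF3 (-1.30 and -1.72) and FKBP10, a collagen chaperone (-1.29 and -1.10). TPM1, which encodes a tropomyosin that coats actin filaments, was at -1.33 and -1.42 and shares exonic sequence with other genes, and so do NIPA1, ALG11, ZNF260, FAM53C and ZBED1, which were named by the same rule, and with the overlapping gene added ALG11 was at -0.07 in MG63. PPAN-P2RY11 is a readthrough locus, and PVRIG2P and SDHAP2 are pseudogenes. Across all 12885 genes the log2 changes of both lines correlated at a Pearson r of 0.170 and a Spearman rho of 0.271, and 60.5% had the same sign, genes not being independent replicates. The shared counts were 14 higher and 31 lower with median-ratio factors, 21 and 14 with each library rescaled to the same FPKM sum, 45 and 56 with a pseudocount of 0.1, and 3 and 1 with 5, where 7 were changed in opposite ways.

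When both lines were fitted together, with the cell line as a block, no single gene passed over all genes tested. The 2 lines are the only replicates of the treatment in this fit, which has 1 residual degree of freedom. By edgeR's quasi-likelihood test 0 of 12885 genes had an adjusted p below 0.05, with 1072 at an unadjusted p below 0.05 and a smallest adjusted p = 0.587. limma on log2(FPKM + 1) called 0 genes (1265 unadjusted, smallest adjusted p = 0.493), and DESeq2 called 278, of which 74 were higher and 204 lower. FBXO34 had an edgeR log2 change of -3.19 ± 0.21 (SE, adjusted p = 0.587), EMP1 1.92 ± 0.21, SAR1A 1.28 ± 0.15, FKBP10 -1.33 ± 0.14 and MMP3 3.38 ± 1.18, all with the same adjusted p.

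Gene lists were tested on the same cross-line fit. Of the 41 lists with at least 5 measured members, fixed before the data were examined, limma camera with a preset correlation of 0.01 called 8 higher and 6 lower with B5. These p-values take genes as replicates and do not measure how a list would vary between cultures. With the correlation estimated from the residuals none of the 14 passed, the adjusted p being 0.947 for the lists of G1/S genes and of cytosolic ribosomal proteins and 0.888 for each of the other 12. In that setting camera takes its p-value from the fit's 1 residual degree of freedom, so hardly any list could pass. Interferon-stimulated genes had an estimated correlation of -0.0161, below the preset 0.01, yet their unadjusted camera p went from 1.55e-06 to 0.115. That setting therefore cannot decide whether a list changed. The other called lists all had estimates above the preset, from 0.0185 for collagens and matrix genes to 1 for G1/S and mitochondrial genome-encoded genes. The estimate was 0.862 for ATF4 and 0.818 for hypoxia genes. Where members of a list vary together by more than the preset allows, camera p-values with the preset may be far too small. The group furthest above the rest was ribosome biogenesis. Of its 27 measured genes 27 were higher in MG63 and 26 in U2OS, with median log2 changes of 0.52 and 0.79 (camera adjusted p = 6.04e-14; adjusted p = 0.888 with an estimated correlation). By edgeR 18 of the 27 passed when adjusted over the list alone and 0 over all genes, with 20 at an unadjusted p below 0.05; limma passed 23 over the list alone and DESeq2 called 9 over all genes. NOP2, a ribosomal RNA methyltransferase (chromosome 12, 6556863 to 6568332), rose when adjusted over the list alone (log2 1.57 in MG63 and 1.04 in U2OS), and so did the ribosome assembly factor RRS1 (log2 1.07 and 1.25). Both overlap exons of another gene, and with the overlapping genes added the NOP2 locus was at 0.32 in MG63 and 1.11 in U2OS and the RRS1 locus at 1.12 and 1.30. MYC itself, a member of this list, was at log2 0.01 in MG63 and -2.47 in U2OS.

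Collagens and other extracellular matrix genes were lower as a group in both lines. Of the 38 measured members 35 were lower in MG63 and 36 in U2OS, 33 of them in both, with median log2 changes of -0.45 and -0.49 (camera adjusted p = 1.16e-17; adjusted p = 0.888 with an estimated correlation). COL3A1, a fibrillar collagen chain (chromosome 2, 188974320 to 189012746), went from 1031 to 528 FPKM in MG63 and from 4.57 to 0.611 in U2OS. COL1A1, the main chain of type I collagen, went from 242 to 160 FPKM in MG63 and from 186 to 43.2 in U2OS, and COL5A1 was at log2 -0.98 and -1.46. SPARC, a matrix glycoprotein abundant in bone, went from 511 to 302 and from 341 to 117 FPKM. By edgeR 0 of the 38 passed when adjusted over the list alone and 0 over all genes, with 21 at an unadjusted p below 0.05; limma passed 0 over the list alone and DESeq2 called 13 over all genes.

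Redox and protein quality control genes were among the higher lists. NRF2 targets had medians of 0.28 in MG63 and 0.35 in U2OS over 27 genes (camera adjusted p = 0.000238; adjusted p = 0.888 with an estimated correlation), and TXNRD1, thioredoxin reductase, went from 22.8 to 93.4 FPKM in U2OS and from 35.1 to 34.4 in MG63. Heat shock genes had medians of 0.51 and 0.35 over 21 genes (camera adjusted p = 0.00279; adjusted p = 0.888 with an estimated correlation). The constitutive chaperone gene HSPA8 went from 231 to 641 FPKM in MG63 and from 312 to 415 in U2OS, while the small heat shock gene CRYAB was lower in both (log2 -0.36 and -0.88). Proteasome subunits had medians of 0.34 and 0.14 over 27 genes, 24 of them higher in both lines (camera adjusted p = 0.00045; adjusted p = 0.888 with an estimated correlation), for example PSMC4 (log2 0.57 and 0.37). The U2OS median lay at percentile 69.0 of its random lists, within their range, and became 0.05 with median-ratio factors. Homologous recombination and Fanconi repair genes had medians of 0.23 and 0.14 over 27 genes, all higher in MG63 and 21 higher in U2OS (camera adjusted p = 0.00502; adjusted p = 0.888 with an estimated correlation), for example RBBP8 (log2 0.52 and 0.51), the U2OS median again lying within its random lists at percentile 66.8 and becoming 0.05 with median-ratio factors. This list did not pass with a mean of at least 5 FPKM (adjusted p = 0.0557). Cytosolic ribosomal protein genes had medians of 0.10 and 0.32 over 48 genes (camera adjusted p = 0.00706, and 0.947 with an estimated correlation). The MG63 value lay at percentile 24.9 of its random lists, that is within their range, and became 0.04 with median-ratio factors. The ribosomal protein list did not pass camera with a mean of at least 5 FPKM either (adjusted p = 0.0595). The ATF4 list passed across both lines (camera adjusted p = 6.17e-05; adjusted p = 0.888 with an estimated correlation) although its MG63 median was 0.06, which became -0.00 with median-ratio factors. The G1/S list passed as higher (camera adjusted p = 0.00404; adjusted p = 0.947 with an estimated correlation) with medians of opposite sign in the lines.

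Lists lower with B5 beside the matrix genes were histone, actin, interferon, hypoxia and mitochondrial genome-encoded genes. Of the 15 listed histone genes only 10 could be tested, and all values are of poly-A RNA. Of these 10, 8 were lower in MG63 and 10 in U2OS, with medians of -0.20 and -0.56 (camera adjusted p = 1.23e-05, and 0.888 with an estimated correlation). HIST1H1C, a linker histone gene, went from 5.28 to 3.25 FPKM in MG63 and from 67.0 to 20.8 in U2OS. Actin cytoskeleton genes had medians of -0.10 and -0.40 over 22 genes (camera adjusted p = 1.23e-05; adjusted p = 0.888 with an estimated correlation), and TPM1 alone passed edgeR when adjusted over that list. With each library rescaled to the same FPKM sum the actin medians became -0.01 and -0.24, while the median of all genes went to 0.12 and 0.21. Interferon-stimulated genes had medians of -0.20 and -0.10 over 30 genes (camera adjusted p = 1.27e-05; adjusted p = 0.888 with an estimated correlation), and IFIT1 went from 56.7 to 40.6 FPKM in MG63 and from 2.78 to 0.780 in U2OS. The same rescaling left interferon medians of -0.11 and -0.01. Hypoxia genes passed as lower (camera adjusted p = 3.93e-05; adjusted p = 0.888 with an estimated correlation) with medians of -0.67 in MG63 and -0.01 in U2OS (-0.60 and 0.10 with the same rescaling), and CA9 and ANGPTL4 passed edgeR when adjusted over the list alone. The U2OS part of the ANGPTL4 result rests on only 11 counts untreated and 3 with B5. CA9, a carbonic anhydrase, went from 7.43 to 0.434 FPKM in MG63 and from 2.28 to 0.0836 in U2OS, and shares exonic sequence with another gene, with which added the locus was at 0.15 and -0.18. The 13 mitochondrial genome-encoded genes had medians of -0.35 and -0.66 (camera adjusted p = 0.00095; adjusted p = 0.888 with an estimated correlation), alongside the smaller mitochondrial share of the counts given above, and MT-CYB went from 5464 to 4036 FPKM in MG63 and from 3796 to 1872 in U2OS. In the 11 of these 14 lists other than ribosome biogenesis, actin and hypoxia, edgeR passed 0 of 310 list places when adjusted over each list alone and 0 over all genes, with 45 at an unadjusted p below 0.05; limma passed 1 over the lists alone and DESeq2 called 24 over all genes.

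**Figure D2:**
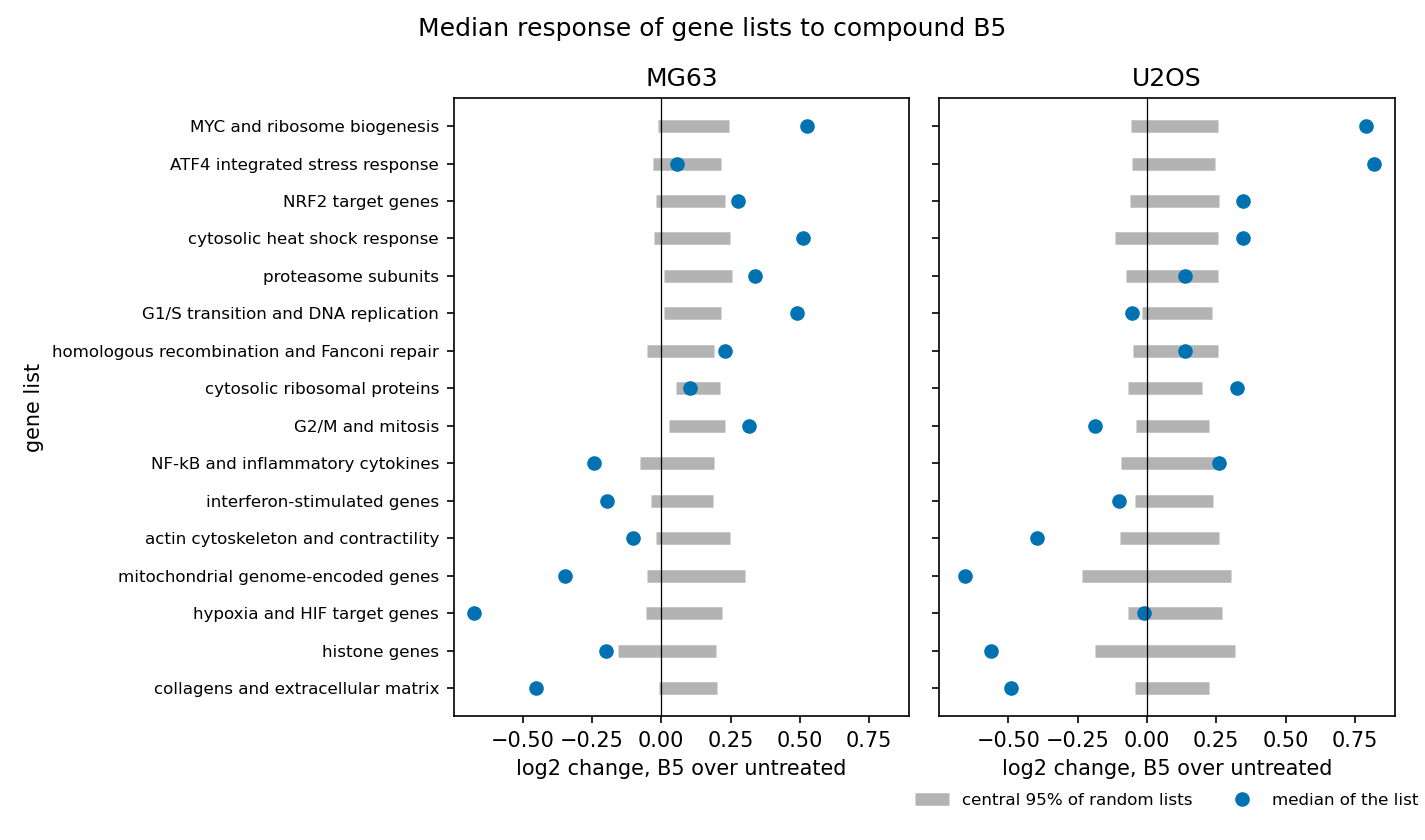
Points give the median log2((FPKM + 1)/(FPKM + 1)) ratio of B5 over untreated for each gene list in MG63 (left) and U2OS (right), and grey bars the central 95% of the medians of 10000 expression-matched random lists. The lists shown are the 14 that passed camera with the preset correlation plus G2/M and NF-kB genes; ribosome biogenesis lies above its bar in both lines (0.52 and 0.79) and collagens and matrix genes below it (-0.45 and -0.49).

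The response to B5 differed most between lines for genes such as TXNIP and MEX3C, which were at least 2-fold changed in opposite ways. TXNIP, which encodes a thioredoxin-interacting protein, went from 18.8 to 5.85 FPKM in MG63 and from 1.71 to 13.2 in U2OS. MEX3C, an RNA-binding ubiquitin ligase gene, went from 0.652 to 3.67 FPKM in MG63 and from 8.75 to 0.801 in U2OS. NDRG1, lower in MG63, had 9.72 FPKM in untreated U2OS and 9.79 with B5, and ANGPTL4 had only 11 counts in untreated U2OS and 3 with B5. In all, 765 genes had log2 changes at least 2-fold apart between the lines, and 21 were at least 2-fold changed in opposite ways. The median difference in response, U2OS minus MG63, was 0.80 for ATF4 genes and 0.70 for hypoxia genes, both at percentile 100 of random lists, and -0.51 for both G1/S and G2/M genes, both at percentile 0. No test of these differences was possible, because a fit with the interaction leaves no residual degree of freedom. The count of 765 became 1388 with a pseudocount of 0.1, 263 with 5, 784 with each library rescaled to the same FPKM sum, and 323 among protein-coding genes without an exon-overlapping gene.

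**Figure D3:**
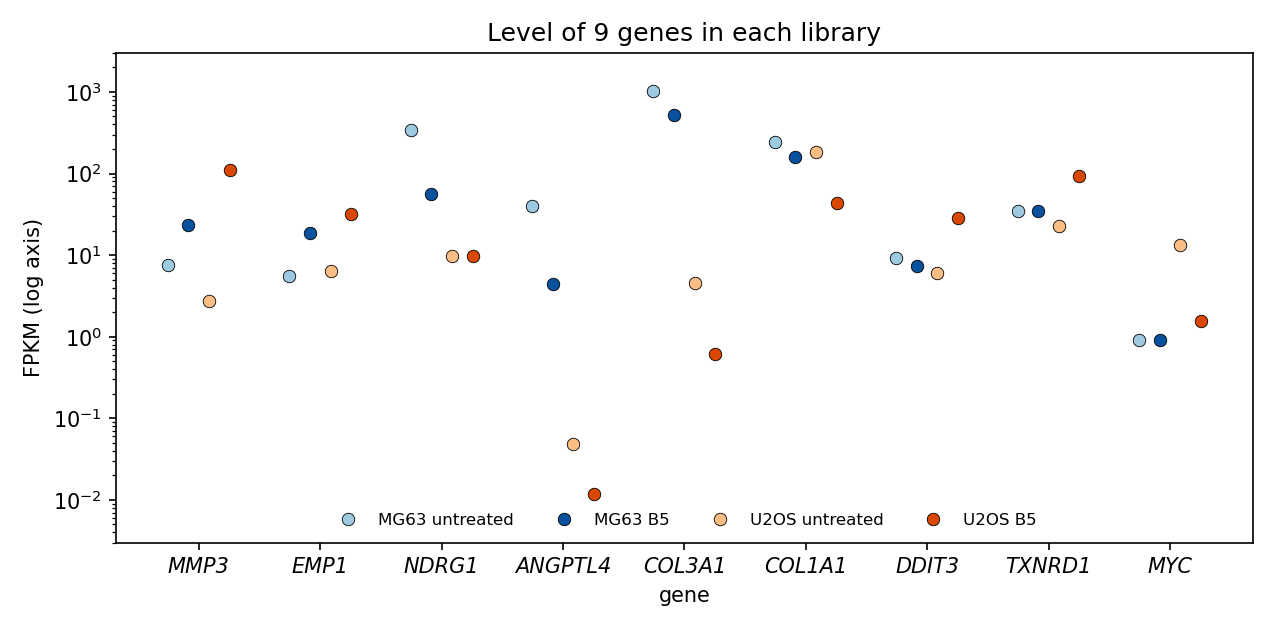
Each point is the FPKM of 1 gene in 1 library on a log axis, for untreated and B5-treated MG63 and U2OS. MMP3 and EMP1 were higher and COL3A1 and COL1A1 lower with B5 in both lines, NDRG1 and ANGPTL4 went from 337 to 56.6 and from 40.4 to 4.44 FPKM in MG63, and DDIT3, TXNRD1 and MYC moved at least 2-fold in U2OS.

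The lines themselves differed in 5126 genes by edgeR. Higher in U2OS were KRT81, a hair keratin gene (chromosome 12, 52285913 to 52291534), with 279 FPKM untreated against 0.461 in MG63, and ANKRD1, a target gene of YAP, with 121 against 0.0407. SFN, which encodes 14-3-3 sigma, had 198 FPKM in untreated U2OS against 0.0308. The cancer-testis genes PAGE2B, PAGE2 and MAGEA4 had 138, 124 and 108 FPKM in untreated U2OS and at most 0.113 in untreated MG63, and PAGE2 and PAGE2B are near-identical copies whose reads the counting may divide. The tubulin gene TUBA3C and the linker histone gene H1F0 followed with 149 and 377 FPKM. Higher in MG63 were COL3A1 and COL1A2, a type I collagen chain, with 220 FPKM untreated against 0.191 in U2OS, and BGN, the proteoglycan biglycan, with 213 against 0.860. BST2 and IFITM1, both interferon-induced membrane proteins, had 401 and 266 FPKM against 1.29 and 0.492. TCF21, a mesenchymal transcription factor, had 190 FPKM against 0.0965, ANPEP, an aminopeptidase, 139 against 0.119, and TNFRSF11B, which encodes osteoprotegerin, 738 against 7.23. By edgeR COL1A2 had a log2 difference, U2OS over MG63, of -10.43 ± 0.26 (SE, adjusted p = 0.0047) and KRT81 of 9.56 ± 0.48 (adjusted p = 0.0057), with the treated and the untreated library as the 2 replicates of each line.

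Of the 12885 genes, edgeR called 2647 higher in U2OS and 2479 higher in MG63. This split of 51.6% higher in U2OS depended on the scaling. It was 51.0% with edgeR on DESeq2-type size factors (2743 and 2632) and 50.4% with DESeq2, but 67.6% with edgeR on library size only (3878 and 1856). With limma, which changes the test as well, it was 66.4% on log2(FPKM + 1) (4080 and 2061) and 47.9% after median-ratio scaling (2847 and 3091). TERT, the catalytic subunit of telomerase, had 64 and 66 counts in untreated and treated MG63 and 0 in both U2OS libraries, where a count of 0 allows up to 0.0393 CPM untreated and 0.0424 with B5. CDKN2B, an inhibitor of CDK4 and CDK6, had 0 counts in both MG63 libraries, which allows up to 0.0374 CPM untreated and 0.0386 with B5, and 1039 and 377 in untreated and treated U2OS. CDKN2A had 0 counts in all 4 libraries.

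Of the genes often used as references, GAPDH and ACTB were lower with B5, in U2OS by as much as some of the lists above. GAPDH had 1848 FPKM untreated and 1704 with B5 in MG63, and 1808 and 1344 in U2OS (log2 -0.12 and -0.43), and ACTB had 541 and 470, and 661 and 505 (log2 -0.20 and -0.39). The 26 measured housekeeping genes, of which 17 were higher in MG63 and 14 in U2OS, had medians of 0.17 in MG63 and 0.01 in U2OS, the latter becoming -0.08 with median-ratio factors, and did not pass camera (adjusted p = 0.865; adjusted p = 0.955 with an estimated correlation). GAPDH, TCF21, IFITM1, MAGEA4, SPARC, HSPA8, CRYAB, RBBP8, DDIT3, SLC7A11, HSP90B1, KIF20A, CCNA2, IDI1 and DDAH1 also share exonic sequence with another annotated gene, and their values are uncertain to that extent.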

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

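The tests of exon number, of median-ratio scaling and of culture conditions were chosen only after the results were seen. The results given first are among those where the lines responded in opposite ways, at least 2-fold for a gene named by the rule, or with medians outside the central 95% of random lists on opposite sides for a gene list. None of these differences was tested, since each line has 1 library per arm. The difference in log2 response, U2OS minus MG63, was 4.51 for ABHD14B, 4.17 for DDAH1, 3.92 for TXNIP and 3.74 for the ferritin pseudogene FTH1P10. It was -3.94 for MEX3C and -8.02 for the mitochondrial pseudogene MTND1P23. ABHD14B and DDAH1 overlap exons of other genes. With those added the ABHD14B locus was at -0.74 in MG63 and 0.99 in U2OS, below 2-fold, which does not tell whether ABHD14B itself changed. The DDAH1 locus stayed at -2.03 and 2.64. The pseudogenes have near-identical copies. The difference between the list medians was -0.54 for G1/S genes and -0.50 for G2/M genes, and 0.50 for NF-kB and inflammatory genes, whose medians were -0.24 in MG63 and 0.26 in U2OS. With each library rescaled to the same FPKM sum the U2OS medians of G1/S and G2/M genes were 0.10 and -0.05 and the NF-kB medians -0.16 and 0.34. The median of all genes was then 0.12 in MG63 and 0.21 in U2OS.

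The first pattern is that 115 genes were at least 4-fold changed in 1 line or both, many of them from or to almost no reads. By the annotation used to find overlaps, 30.4% of them (35 genes) are protein-coding and overlap no other gene's exons. The deposited gene models differ from that annotation for some genes, such as GPX1, and overlaps in the deposited models were not tested. Reads moved between overlapping genes, as the cause for all 115, are therefore argued against only under the gene models used. Overlapped, readthrough or pseudogene loci made up 67.0% of the 115, 1.33 times the 50.4% in the median of expression-matched random sets. That was above the upper limit of the central 95% of these sets (59.1%), but below the 1.5 times set beforehand. Partners moved the other way for only 36.1% of the 72 overlapped genes, so the share of moved reads in the pattern stays open. Among the 35 genes, 22.9% had 3 or fewer exons against 11.4% in random sets, a ratio of 2.00 that did not exceed the upper limit of the central 95% of the random sets, so few-exon genes counted in separate pieces may contribute and this too stays open. A response to B5 stays open for the genes that overlap no other, without a replicate to separate it from the spread between cultures.

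The second pattern is that collagens and extracellular matrix genes were lower with B5 in both lines. Gene length bias is argued against, because 0% of 10000 random lists matched on exon length and expression had a median as low as -0.44. GC content bias is argued against in the same way, with 0% of lists matched on GC content. Median-ratio scaling could not test for a shift of all genes, or for counts given up to a few abundant genes. It moved B5 values down in both lines, so the list medians could only fall, to -0.52 in MG63 and -0.55 in U2OS. Rescaling to the same FPKM sum moved B5 values up and gave -0.36 and -0.43, against 0.12 and 0.21 for the median of all genes. The list lay below all genes under both scalings, which argues against either explanation alone. The pattern is consistent with a lower matrix programme after B5, as a hypothesis found and tested on the same data, and density or growth state of the cultures remains open beside it.

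The third pattern is that hypoxia genes were lower with B5 in MG63 and stayed near their untreated level in U2OS. A level too low to be measured in U2OS is argued against as the whole cause. The 13 list members with at least 5 FPKM in untreated U2OS had a median of -0.54 in MG63 and -0.02 in U2OS, a ratio of 0.042. That limit does not show that these genes were as active in untreated U2OS as in MG63. The list's median untreated level was 7.82 FPKM in U2OS and 13.9 in MG63, so a lower starting level stays open. Oxygen supply or cell density of the MG63 cultures may have differed between the arms, and with 1 library per arm and line this cannot be told apart from an effect of B5. The difference between the lines itself was not tested.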

How the results depend on the processing

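DESeq2, edgeR with other scalings, camera on the counts, rescaling to the same FPKM sum and the subset of genes without an overlapping gene were chosen after seeing the data. No library could be left out and no other split of the samples drawn, because each group holds 1 library and the cross-line fit has 1 residual degree of freedom. Counts are given in the order higher in MG63, lower in MG63, higher in U2OS, lower in U2OS, higher in both, lower in both, at least 2-fold apart between lines; the main values are 139, 163, 278, 268, 18, 24 and 765. A pseudocount of 0.1 gave 285, 345, 503, 480, 45, 56 and 1388, and one of 5 gave 49, 51, 72, 76, 3, 1 and 263, since the pseudocount sets how far genes with low values can move. With a mean of at least 5 FPKM, which tests fewer genes, they were 71, 88, 129, 145, 7, 11 and 392. With a 3-fold threshold they were 41, 54, 80, 80, 2, 4 and 257. Among protein-coding genes without an exon-overlapping gene, again fewer genes, they were 50, 69, 113, 119, 7, 7 and 323. Rescaling to TPM gave 268, 235, 638, 300, 45, 28 and 1181, and changed the scaling and the weight of the pseudocount together. Rescaling to the same FPKM sum, with that weight kept, gave 161, 144, 423, 201, 21, 14 and 784, so the share of higher genes moved with the scaling and the number apart did not. Median-ratio scaling gave 131, 203, 204, 298, 14, 31 and 765. The correlation between lines stayed between 0.144 and 0.233 in every setting in which it was computed.

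B5 across both lines gave 0 genes by edgeR and limma in every setting run, with the unadjusted counts from 566 to 1978 where the cell line was a block. With no replicate block, that is with the cell line left out, edgeR and limma also gave 0, with 53 and 56 at an unadjusted p below 0.05. DESeq2 gave 278, and the cause was not tested. For U2OS against MG63, 2647 genes were higher in U2OS in the main fit and 4080 with limma, 4158 with limma and a pseudocount of 0.1, 4870 with limma after rescaling to TPM, 4719 with limma after rescaling to the same FPKM sum, 4018 without the trend and 4082 with the robust prior. The number followed the scaling, being 2847 with limma after median-ratio scaling and 3878 with edgeR on library size only. edgeR without a filter gave 1568 higher in U2OS and 1602 higher in MG63, and the cause was not tested. It gave 1387 and 1414 with at least 5 FPKM and 1477 and 1363 without overlapping genes, from fewer genes.

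Of the 14 gene lists called, 0 passed with an estimated correlation. That setting takes both the correlation and the p-value from the fit's 1 residual degree of freedom, so it cannot decide whether a list changed. The number passing was 15 with a pseudocount of 0.1, 15 with median-ratio scaling, 13 with at least 5 FPKM and 16 with camera on the counts. With at least 5 FPKM, cytosolic ribosomal proteins (adjusted p = 0.0595) and Fanconi repair (0.0557) no longer passed and histone genes had too few members to be tested, while chaperones of the endoplasmic reticulum (0.00751) and senescence-associated factors (0.0322) passed. Osteoblast genes passed with a pseudocount of 0.1 (0.0337) and on the counts (0.0111), and metallothioneins with median-ratio scaling (0.0292) and on the counts (0.0323). Of the values for named genes 89 moved beyond counting error and 59 did not under a pseudocount of 0.1, and 45 moved and 103 did not under median-ratio scaling; none changed sign among those at least 2-fold changed.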

Other observations

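Several gene groups outside the lists called in the main setting differed from random lists in 1 line. Anti-apoptotic genes had a median log2 change of 0.50 in U2OS at percentile 99.9, with BIRC2 at log2 1.40, and metallothioneins 0.69 at percentile 99.95, with MT2A, a metal-binding protein gene, at log2 1.07 (camera adjusted p = 0.345 and 0.0608; adjusted p = 0.888 for both with an estimated correlation). The MG63 medians of these lists were 0.06 and 0.15. Tubulin genes had a median of 0.39 in MG63 at percentile 99.9 and -0.10 in U2OS (0.05 with each library rescaled to the same FPKM sum), with TUBB6 at log2 1.99 in MG63, though tubulin genes have near-identical copies (camera adjusted p = 0.865). CCL2, a monocyte-attracting chemokine, had 93.5 FPKM untreated and 48.2 with B5 in MG63, and 12.3 and 4.11 in U2OS. IGFBP3, an insulin-like growth factor binding protein, was at log2 -1.54 in MG63 and -0.03 in U2OS, and TGFBI, a matrix protein induced by TGF-beta, at -1.15 and -0.90. RUNX2, the transcription factor of osteoblast commitment, was at 0.03 in MG63 and -1.60 in U2OS, and SPP1, osteopontin, at -0.24 and 1.57. Their osteoblast list of 14 genes had medians of -0.08 and -0.20 (camera adjusted p = 0.0834, and 0.888 with an estimated correlation). After that rescaling the list medians were -0.04 and -0.09, while the median of all genes went to 0.12 and 0.21.

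Markers of other cell types gave few measured genes. Of the leukocyte list 1 gene had a mean of at least 1 FPKM, CD68, of the endothelial list 1, ERG, of the adipocyte list 2, of the skeletal muscle list 1, TNNT1, and of the neural list 3.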
